A study of Mus musculus with 2 samples.

How the data were processed

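Ribosomal RNA-depleted total RNA of the nucleoplasmic fraction was sequenced from 2 cultures of mouse bone marrow-derived macrophages stimulated with Lipid A, per the labels. The labels number the libraries as biological replicates 1 and 2, give them separate biosample entries, and name the same donor entry for both. They form 1 group, so the spread between them is the only measure of error, and no comparison between groups, paired or not, could be made.

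For each library the authors deposited a gene table and a transcript table made from a transcriptome alignment, and a further transcript table made from the read files, per the labels' accompanying notes. The genome was mm10 with annotation M21, per the same notes. The aligner, the quantification tools and their versions, and whether counting used strand, are not given in the sources used here; the column names are those that RSEM and kallisto write. The deposited expected counts are estimated counts per gene or transcript that need not be whole, per the file headers and values. The deposited TPM values are abundances divided by effective length and scaled to one total over all entries of a table, per the file headers. The deposited FPKM values, fragments scaled by effective length and depth, per the file headers, entered only as an alternative.

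Division by effective length weighs on these libraries. RNA not much longer than the fragments has a very short effective length, and small RNA then takes a large part of the TPM. Nuclear-encoded protein-coding genes held 72.6% and 67.1% of counts but 29.7% and 20.8% of TPM. A gene's TPM therefore moves with the small RNA of its library, and shares of the library are given in counts. The gene tables held 55536 genes, all found in the GENCODE M21 annotation used for coordinates and gene classes, which matches the build of the files. They also held 26248 entries with a number as identifier, 96 ERCC spike-ins and the phiX174 genome. These 3 kinds carry no gene name in the files and were kept out of all lists and tests, and together they took 1.41% and 0.245% of counts. ERCC spike-ins had 0 counts in both libraries, which allows up to 3 counts each.

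The totals were 14374739 and 16372797 estimated counts in the gene tables, and 20813687 and 27466816 in the read-based table. Shares of counts carry 95% Wilson intervals, which cover counting error only because reads without molecular identifiers are not independent molecules. A count of 0 was taken to allow 3 counts, which for a transcript of 1 kb is 0.213 TPM in replicate 1 and 0.141 TPM in replicate 2.

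Genes were called detected at 1 TPM or more in both libraries. Agreement was measured over genes with 10 or more rounded counts in both, as correlations across genes of log2(TPM + 1), the SD of the log2 ratio, and the common biological coefficient of variation from edgeR 4.0.16 with an intercept-only design on expected counts rounded to whole numbers. DESeq2 1.42.0 served for an alternative scaling, in R 4.3.3. Other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. A chi-square test of the count columns asked only whether they were 1 library deposited under 2 names.

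Before the data were examined, 30 gene lists with 489 symbols were fixed, of which 488 matched a gene. They comprised 7 toll-like receptor response lists, macrophage, metabolic, RNA class and cell cycle lists, and 10 lists of markers of other cell types. Where several genes share a symbol, the one with most counts was used. A list's level is the median over members of mean TPM, placed among 10000 random lists of the same size. A list's difference between replicates is the median over members at a mean TPM of 1 or more of log2((TPM + 1) in replicate 2 over (TPM + 1) in replicate 1), minus the median of all such genes, placed among 10000 random lists matched on mean expression in 10 bins; lists with under 3 members there have no value. The pseudocount of 1 understates differences of low genes. The retained-intron share of a gene is the share of its transcript TPM in transcripts annotated as retained_intron, over protein-coding genes at 5 TPM or more in both that have such a transcript. The rule fixed in advance had no limit to protein-coding genes, so its values over 3818 genes of any class are given in the closing section. That rule would also have named Mx2 in place of Nfkb2 for a low share. Another 4 lists were added after the data were seen (proteins made at the endoplasmic reticulum, soluble intracellular proteins, lysosome, fibroblast matrix) and serve only the closing observations.

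Named genes follow a rule fixed before the data were examined. It takes the 3 highest members of each list other than marker lists, the lowest member of each response list, the highest member of each marker list, the 10 highest protein-coding and 5 highest long noncoding genes, and the 5 largest differences in each direction among protein-coding genes with 100 or more counts in both. It adds Ifnb1, Tnf, Il6, Il12b, Nos2, Nfkbia, Malat1 and Neat1, and the 3 response genes with the highest and the 3 with the lowest retained-intron share. This gave 99 genes, of which a few are not reported here. Small RNA and RNA class entries were singled out after their values were seen. Overlapping genes and close copies share reads whose division is uncertain.

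The scripts were tested on simulated data. For replicate 2 against replicate 1, biological coefficients of variation of 0.1, 0.2 and 0.4 came back as 0.0996, 0.198 and 0.389 over 13211, 13138 and 12864 genes. Over 12655 genes, lists of 20 genes fell outside the percentile limits in 10% of 50 simulations with no difference, and in 50%, 94% and 100% with a difference of 1.2-fold, 1.5-fold and 2-fold. Alternatives covered the pseudocount, filters on low values, TMM and DESeq2 scaling, FPKM, the read-based table, counts without length, the background of random lists, matching on length and GC content, and each library alone.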

Results

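The series held ribosomal RNA-depleted total RNA sequencing of 2 libraries from mouse macrophages grown from bone marrow of strain C57BL/6J. The cells had been stimulated for 120 min with Lipid A at 100 ng/ml. Lipid A is the part of bacterial lipopolysaccharide that is sensed through the receptor Tlr4. RNA came from the nucleoplasmic fraction, the soluble part of the nucleus, although 1 label field names the fraction only as nucleus. The libraries were biological replicates 1 and 2 of 1 group, and their labels give an RNA input of 1 µg and 500 ng. Input and replicate therefore cannot be told apart. The gene tables held 14374739 estimated counts in replicate 1 and 16372797 in replicate 2. No untreated culture, other time point or other cell fraction was analysed here, so a level below is not an induction, and no test between groups exists.

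RNA of inflammatory response genes was abundant in both libraries. Of 138 genes in 7 lists of toll-like receptor response genes, 127 reached 1 TPM (transcript abundance scaled to one total in every library) or more in both replicates. The interferon response list stood highest among these 7, with all 28 members detected and a median of 241.7 TPM over members. Its leading genes were the antiviral Rsad2 (chromosome 12, 26442746 to 26456452 in mm10) at 1853 ± 225 TPM and Mx1 (chromosome 16, 97447035 to 97462907) at 1814 ± 627 TPM (SD, n = 2, here and below). Mx2, annotated as a polymorphic pseudogene, followed at 1009 ± 444 TPM. Its members other than Mx2 held 4.34% of the TPM of nuclear-encoded protein-coding genes in replicate 1 and 4.48% in replicate 2. Its lowest member was the type I interferon gene Ifnb1 itself (chromosome 4, 88522025 to 88522774), at 16.2 ± 0.629 TPM from 118 and 188 counts. Each SD of TPM includes a shift between the libraries, with a median log2 ratio of -0.58 over genes at a mean of 1 TPM or more. A small SD therefore need not mean close replicates. Relative to that median, Ccl5 below differed by a log2 of 0.55 despite a small SD, and Tnf by 0.01 despite a larger one.

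Genes that restrain or carry nuclear factor kappa B (NF-kB) signalling were the next highest of the 7 lists. All 17 members were detected, with a median of 92.6 TPM (136 in replicate 1 and 58.8 in replicate 2). Tnfaip2 reached 1326 ± 584 TPM, Tnip3 reached 767 ± 406 TPM, and Tnfaip3, which encodes the A20 inhibitor of the pathway, reached 636 ± 236 TPM. Nfkbia (chromosome 12, 55489410 to 55492647), which encodes the inhibitor that holds NF-kB in the cytoplasm, stood at 391 ± 200 TPM. The deubiquitinase gene Cyld was the lowest member at 17.2 ± 6.00 TPM. Feedback regulators outside this list had a median of 32.6 TPM (45.7 in replicate 1 and 19.6 in replicate 2) with 18 of 18 detected, led by the cytokine signalling suppressor Socs3 at 241.6 ± 96.3 TPM, Gadd45b at 241.0 ± 96.7 TPM and the phosphatase gene Dusp2 at 206 ± 77.2 TPM. Phlda1 was lowest there at 2.67 ± 1.89 TPM.

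Chemokine genes had a median of 59.0 TPM, with 15 of 16 detected in both libraries. Cxcl10 (881 ± 142 TPM), Ccl5 (784 ± 14 TPM) and Ccl4 (549 ± 26.3 TPM), which attract T cells and monocytes, led this list. The neutrophil attractant gene Cxcl3 was lowest at 1.14 ± 0.629 TPM. Cytokine genes had a median of 42.4 TPM, with 13 of 18 detected in both. Tnf (chromosome 17, 35199381 to 35202007) was highest at 333 ± 93.3 TPM, followed by Il15 at 252 ± 124 TPM and Tnfsf9 at 193 ± 15.9 TPM. In the transcript table made from the read files, called the read-based table here, Il15 (789 TPM) stood above Tnf (209.3 TPM). Il12b stood at 48.1 ± 0.785 TPM and Il6 at 17.2 ± 3.86 TPM. Csf3, the granulocyte growth factor gene, had only 2 and 3 counts (0.120 TPM in each library), at or under the 3 counts taken as the floor.

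Secondary effector genes had a median of 19.7 TPM with 20 of 23 detected. Cd40, a costimulatory receptor, stood at 252 ± 91.4 TPM, the itaconate-producing enzyme gene Acod1 at 228 ± 65.8 TPM, and the superoxide dismutase gene Sod2 at 147 ± 84.5 TPM. Nos2, which encodes the inducible nitric oxide synthase, was at 20.3 ± 3.20 TPM. The formyl peptide receptor gene Fpr1 was lowest at 0.375 ± 0.290 TPM. The immediate early list was the lowest of the 7, at a median of 8.20 TPM (10.5 in replicate 1 and 5.15 in replicate 2) with 16 of 18 detected. Klf6 (147 ± 51.1 TPM), Zfp36 (98.5 ± 23.7 TPM) and Junb (79.9 ± 42.0 TPM) led it, and Egr3 had 1.2 ± 0.544 TPM.

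Genes of macrophage identity and of Tlr4 signalling were abundant, while genes of alternative activation mostly were not. Macrophage identity genes had a median of 81.1 TPM with 23 of 25 detected. The cathepsin genes Ctsb (1006 ± 556 TPM) and Ctsd (729.9 ± 555 TPM) and the lysozyme gene Lyz2 (859 ± 646 TPM) were highest. The Tlr4 pathway list had a median of 21 TPM with 23 of 23 detected, led by the kinase gene Ikbke (560 ± 317 TPM), the coreceptor gene Cd14 (188 ± 114 TPM) and Map3k8 (124 ± 58.7 TPM). The other toll-like receptors had a median of 16.2 TPM with 8 of 11 detected, led by Tlr2 (118 ± 31.0 TPM), Tlr1 (74.1 ± 12.2 TPM) and Tlr7 (45.0 ± 15.2 TPM), an order that turned in the read-based table (70.2, 73.5 and 83.9 TPM). Of 11 alternative activation genes, 2 were detected in both libraries, and the list's median was 0.465 TPM (0.590 in replicate 1 and 0.240 in replicate 2). Il4ra, the interleukin 4 receptor gene, was the exception at 212 ± 110 TPM, ahead of Clec10a (5.14 ± 2.05 TPM) and Chil3 (0.970 ± 0.537 TPM).

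Metabolic and structural lists gave the background to these levels. Splicing factor genes had a median of 101 TPM with 26 of 26 detected, led by Ddx5 (381 ± 55.7 TPM), Srsf5 (297 ± 170 TPM) and Srrm2 (294 ± 184 TPM). Cytosolic housekeeping genes had a median of 66.8 TPM, led by the actin gene Actb (756 ± 34.6 TPM) and the ferritin genes Fth1 (664 ± 67.6 TPM) and Ftl1 (599 ± 34.4 TPM). Ribosomal protein genes had a median of 33.9 TPM, with Rps24 (96.9 ± 21.1 TPM), Rpl10 (83.8 ± 9.96 TPM) and Rps9 (82.8 ± 23.2 TPM) at the top. Glycolysis and hypoxia genes had a median of 18.8 TPM, led by Hk3 (250.6 ± 107 TPM), Pfkfb3 (145 ± 90.5 TPM) and Pfkp (127 ± 98.3 TPM). Targets of the sterol-sensing liver X receptors had a median of 16.2 TPM, led by Apoe (381 ± 151 TPM), Pltp (120.1 ± 21 TPM) and Abca1 (92.5 ± 13.9 TPM). Cholesterol synthesis genes had a median of 5.80 TPM, and Insig1 stood at 37.8 ± 1.41 TPM. The cell cycle list had a median of 0.870 TPM with 9 of 23 detected, and Pcna (30 ± 2.19 TPM), Mki67 (28 ± 9.74 TPM) and Mcm6 (7.72 ± 0.332 TPM) stood above it.

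**Figure D1:**
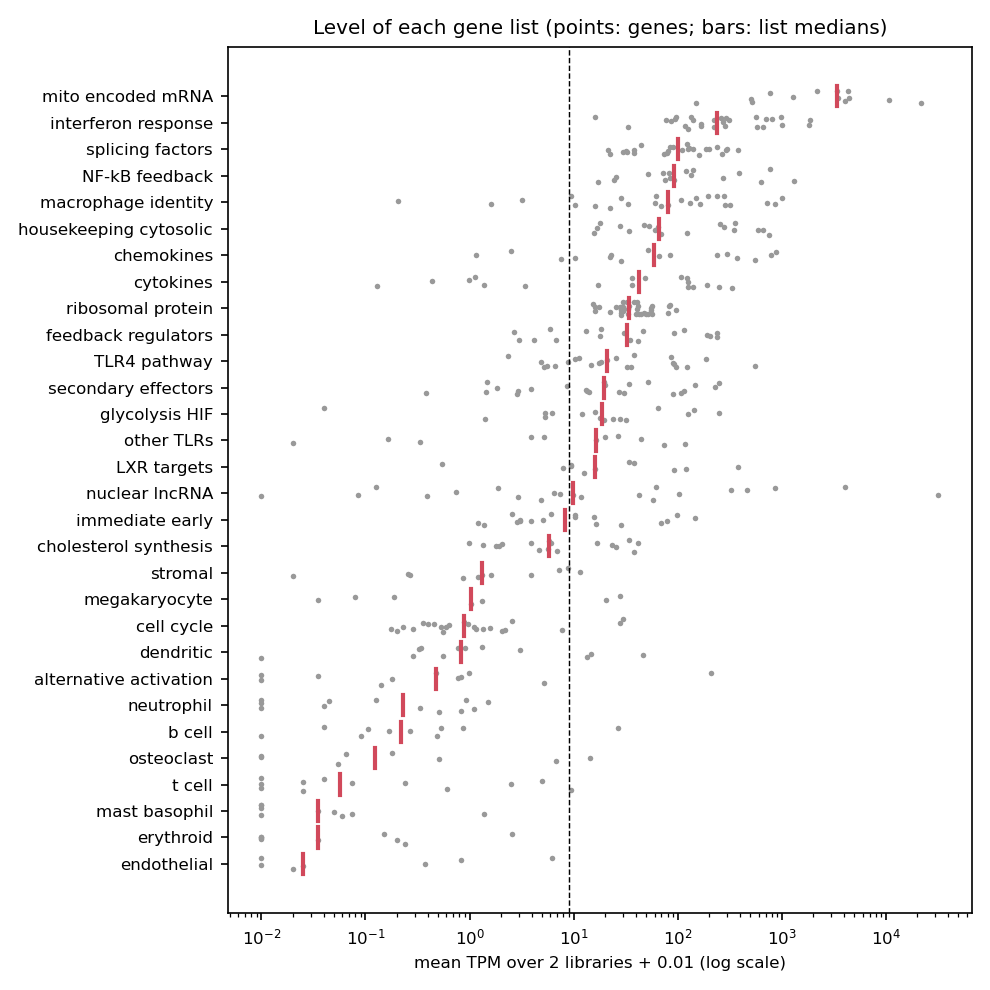
Mean TPM of the 2 libraries plus 0.01, on a log axis, for the members of each of the 30 gene lists. Points are genes, red bars are list medians, and the dashed line is the median of protein-coding genes detected in both libraries (9.08 TPM). Mitochondrially encoded mRNA (3438 TPM, from list medians of 305 in replicate 1 and 6384 in replicate 2), interferon response (241.7 TPM) and splicing factor genes (101 TPM) lie at the top, and most marker lists of other cell types lie below 1 TPM.

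Against 10000 random lists of the same size drawn from measured protein-coding genes, or from all genes for nuclear long noncoding RNA, 18 of the 30 lists lay above percentile 95, 12 lay between, and 0 lay below percentile 5. All 7 response lists were among the 18. Much of this background is silent in macrophages. A second background held only genes at 1 TPM or more in both libraries, again protein-coding except for nuclear long noncoding RNA. Against it, immediate early genes lay at percentile 38.1, other toll-like receptors at 86.8 and nuclear long noncoding RNA at 71.1. Cholesterol synthesis lay at 11.7 and liver X receptor targets at 87.5, so these 5 lists no longer stood high. With members held to the same limit, nuclear long noncoding RNA (100) and liver X receptor targets (96.7) still stood high. The 12 lists in between, which were alternative activation, cell cycle and the 10 marker lists, lay at percentile 0 of this background, for 10 of them by construction, as their medians lie below 1 TPM. With members held to the limit, cell cycle lay at 0.140 and dendritic cell at 63.8, and the other 10 had too few members.

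Markers of other cell types were mostly low, and several differed between the libraries. The T cell list had a median of 0.0475 TPM, B cell 0.210, neutrophil 0.220, dendritic cell 0.828, erythroid 0.0250, mast cell and basophil 0.0250, megakaryocyte 1.02, endothelial 0.0150 and osteoclast 0.112 TPM. Some of these medians describe neither library, since replicates 1 and 2 had 1.66 and 0.110 TPM for megakaryocyte, 1.32 and 0.340 for dendritic cell, and 0.300 and 0.0750 for B cell genes. The erythroid and the mast cell and basophil medians were 0 in each library. Their highest members were Cd4 (9.36 ± 7.33 TPM), Blnk (26.5 ± 9.17), Ltf (1.51 ± 1.47), Cd74 (46.3 ± 11.7), Alas2 (2.54 ± 1.17), Kit (1.36 ± 1.01), Pf4 (28.1 ± 19.2), Kdr (6.18 ± 1.90) and Acp5 (14.2 ± 3.17 TPM). Macrophages themselves express several of these, among them Cd74 and Acp5. The stromal list, which holds fibroblast collagen genes, had a median of 2.63 TPM in replicate 1 and 0.0200 TPM in replicate 2. Its highest gene, Col1a1 (chromosome 11, 94936224 to 94953042), had 1845 counts in replicate 1 and 8 in replicate 2. Over the 11 stromal genes the totals were 4808 and 30 counts.

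The libraries differed in their RNA classes. Nuclear-encoded protein-coding genes held 72.6% of counts in replicate 1 and 67.1% in replicate 2 (69.8 ± 3.88%), although 29.7% and 20.8% of TPM, which division by length tilts toward short RNA. Mitochondrially encoded genes held 0.424% (95% Wilson interval 0.421 to 0.428) and 8.70% (8.69 to 8.71), a 20.5-fold ratio. Every interval here covers counting error only. Long noncoding genes held 19.4% and 13.0%, of which Malat1 (chromosome 19, 5795690 to 5802672), a nuclear speckle RNA, took 12.7% and 9.95% of all counts. The 7SK RNA gene Rn7sk, which restrains transcription elongation, held 0.338% and 3.48%. Gm26917, annotated as a lincRNA gene, went the other way, with 2.06% and 0.414%. Small nuclear RNA held 0.286% and 0.167%, small nucleolar RNA 0.0925% and 0.0285%, ribozymes 0.771% and 1.37%, and ribosomal protein genes 0.170% and 0.188%. The miscellaneous RNA class, which contains Rn7sk, held 0.899% and 4.50%, and loci of the annotation class TEC, whose existence awaits experiment, held 2.76% and 1.62%. The 10 genes with most counts took 20.8% and 23.5%, and the top 100 took 36.3% and 44.2%.

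**Figure D2:**
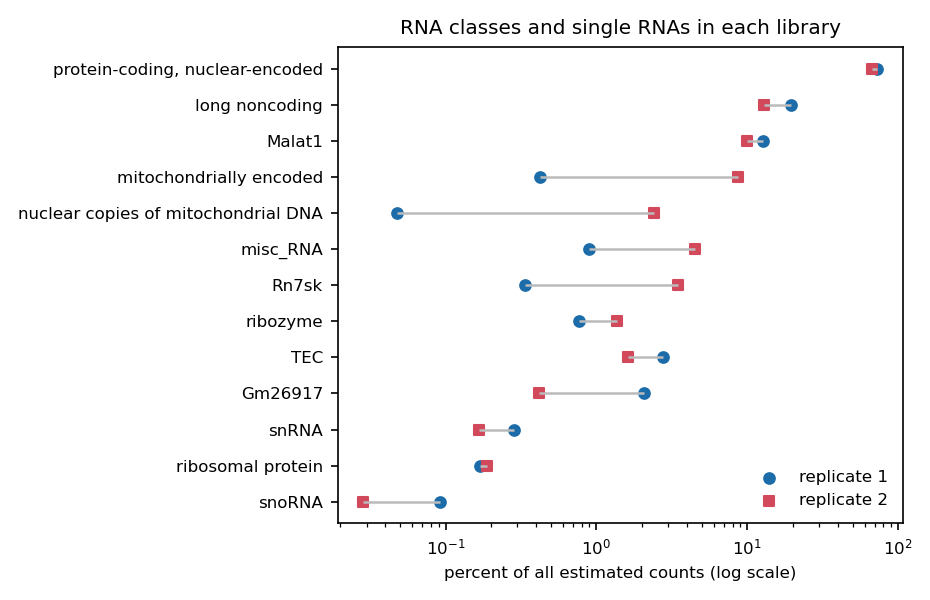
Share of all estimated counts, in percent on a log axis, held by RNA classes and single RNAs in replicate 1 (circles) and replicate 2 (squares). Classes can overlap, since Malat1 and Gm26917 are long noncoding, Rn7sk is a misc_RNA, and TEC marks loci whose existence awaits experiment. Mitochondrially encoded RNA lay at 0.424% and 8.70%, and nuclear-encoded protein-coding RNA lay at 72.6% and 67.1%.

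Among long noncoding genes the 5 highest were Malat1 (31942 ± 10450 TPM), a lincRNA annotation of Rmrp (24418 ± 28736 TPM), Gm26917 (4031 ± 4252 TPM), Gm42418 (1738 ± 1638 TPM) and the paraspeckle RNA Neat1 (855 ± 368 TPM). The nuclear long noncoding list of 21 genes had a median of 9.88 TPM (13.5 in replicate 1 and 6.25 in replicate 2) with 15 detected in both. The Rmrp value is uncertain, since this annotation overlaps a ribozyme gene of the same name, and Gm42418 overlaps an annotated ribosomal RNA on the other strand. Gm26917 ends at 39846341 on chromosome 17, shortly before Gm42418 starts at 39846958. Both were lower in replicate 2, with log2 ratios relative to the median gene of -2.20 for Gm26917 and -1.74 for Gm42418. Whether ribosomal RNA left after depletion adds to either value was not tested. All 8 of the mitochondrial genes below were among the 10 highest protein-coding genes, next to Psap (1901 ± 1072 TPM) and Rsad2. They were mt-Atp8 (21939 ± 30384 TPM), mt-Co1 (10814 ± 13199), mt-Nd6 (4414 ± 5360), mt-Nd1 (4372 ± 5837), mt-Cytb (4089 ± 5350), mt-Nd4 (3446 ± 4348), mt-Nd5 (3438 ± 4165) and mt-Nd2 (2177 ± 2880). Each SD exceeded its mean, so these means describe neither library. The first place of mt-Atp8 rests on division by the length of a short gene (7766 to 7969). It had 159 and 20180 counts in replicates 1 and 2, against 27703 and 568369 for mt-Co1. In the read-based table mt-Co1 (6397 TPM) stood above mt-Atp8 (5097 TPM). Reads of mt-Atp8 and mt-Atp6 overlap, and 7 unprocessed pseudogenes of mitochondrial sequence on chromosome 1 held 0.0475% and 2.4% of counts.

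Across genes the replicates correlated closely. Over 13420 genes with 10 or more counts in both, the correlation across genes of log2(TPM + 1) was 0.956 (Pearson) and 0.953 (Spearman); genes are not independent replicates. Over 10644 nuclear-encoded protein-coding genes, a set chosen after seeing the data, it was 0.963 and 0.960. The SD of the log2 ratio over the 13420 genes was 0.58, and edgeR gave a common biological coefficient of variation of 0.305. The counts differed by far more than sampling noise (chi-square over degrees of freedom 238), so they are not 1 library deposited under 2 names. At 1 TPM or more in both libraries there were 11216 genes, of which 8905 were protein-coding and 707 long noncoding, while 2114 reached it in replicate 1 alone and 290 in replicate 2 alone. At 5 TPM the count was 6240. The lower TPM of most genes in replicate 2 (median log2 ratio -0.58) enters the imbalance at 1 TPM, as TPM was not rescaled there. Replicate 1 also had more genes with a count above 0 (22047 against 19664).

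**Figure D3:**
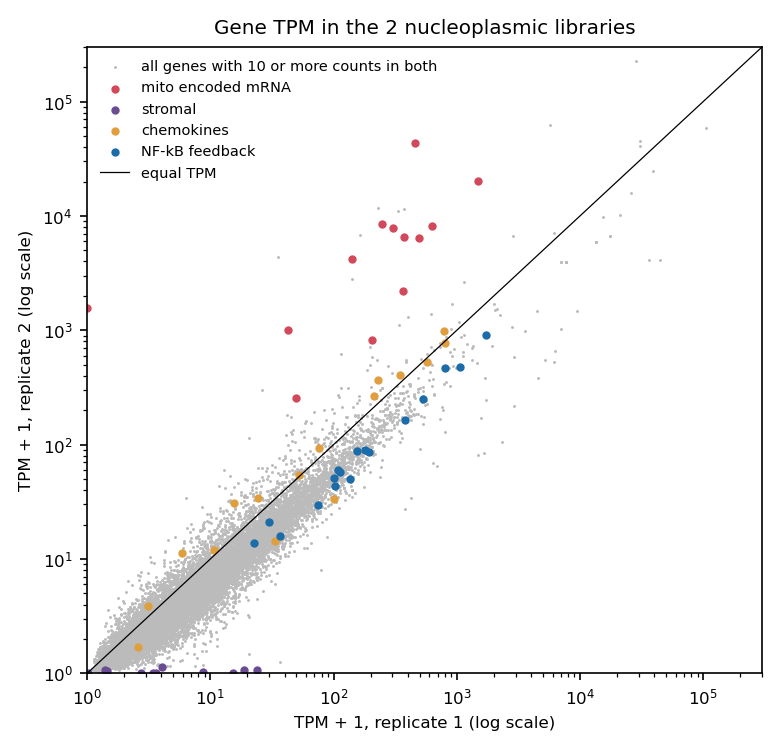
TPM + 1 of each gene in replicate 1 (horizontal) and replicate 2 (vertical), both on log axes. Grey points are the 13420 genes with 10 or more counts in both libraries, coloured points are members of 4 lists, and the line marks equal TPM. Mitochondrially encoded genes lie far above the line, stromal genes lie near the bottom, and most other genes lie below the line, with a median log2 ratio of -0.50.

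Replicate 2 held relatively more RNA of mitochondrial genes, macrophage identity genes, toll-like receptors and chemokines, and less of NF-kB regulators and stromal genes. Since the TPM of all genes at a mean of 1 or more was shifted by a median log2 of -0.58, every ratio here is relative to that median, and scaling by TMM or by DESeq2 size factors leaves medians of 0.02 and -0.01. The mitochondrially encoded list had a median relative log2 ratio of 4.71, with 13 of 13 members higher in replicate 2. The largest increases among protein-coding genes with 100 or more counts in both were mt-Atp8 (7.16), mt-Nd1 (5.70), mt-Nd2 (5.48), mt-Cytb (5.27) and mt-Nd4 (4.71). The other toll-like receptors stood at 1.10 (8 of 8 higher), with Tlr7 at 1.27 and Tlr2 at 1.12. Chemokines stood at 0.84 (13 of 16 higher), with Cxcl10 at 0.91 and Ccl5 at 0.55. Macrophage identity genes stood at 0.80 (18 of 24 higher), with Ctsd at 2.31, Lyz2 at 2.29 and Ctsb at 1.77.

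Further lists were higher in replicate 2 by smaller amounts. Cytosolic housekeeping genes stood at 0.69 (18 of 18 higher), cholesterol synthesis at 0.58 (14 of 16), ribosomal protein genes at 0.47 (32 of 38) and liver X receptor targets at 0.43 (6 of 10). The T cell list stood at 0.70 over 3 members, which were Cd4 (2.17), Lck (0.70) and Cd5 (-1.56, from 106 and 10 counts), the last 2 named after their values were seen. It fell inside the limits with TMM scaling (percentile 89.1), DESeq2 scaling (89.3) and no filter on low values (84.2). The dendritic cell list stood at 0.55 over 5 members. Interferon response genes stood at 0.16 (19 of 28 higher). Without a filter on low values the subtracted median was -0.31, and interferon response genes stood at -0.12, still at percentile 99.8 of matched lists. Dendritic cell genes stood at -0.17 there, at percentile 35.9.

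Lower in replicate 2 were the stromal list at -2.51 (7 of 7 lower, all below 1 TPM in replicate 2), NF-kB feedback genes at -0.43 (16 of 17 lower) and nuclear long noncoding genes at -0.34 (13 of 16 lower). Nfkbia stood at -0.51, Tnip3 at -0.55 and Tnfaip2 at -0.35. Among protein-coding genes with 100 or more counts in both, the largest decreases were Glp2r (-1.83), Gdf15 (-1.76), Gm16867 (-1.71), Zbed6 (-1.69) and Myo10 (-1.41), of which Zbed6, Gm16867 and Myo10 overlap other annotated loci on their strand, and Glp2r and Gm16867 overlap loci on the other strand. The remaining 9 lists lay inside the limits. They were cell cycle (0.36), cytokines (0.15), Tlr4 pathway (-0.05), secondary effectors (-0.05), glycolysis and hypoxia (-0.10), immediate early (-0.11), feedback regulators (-0.27), splicing factors (-0.28) and megakaryocyte (-0.30). Tnf at 0.01, Il6 at 0.15 and Acod1 at -0.01 differed little between the libraries.

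A list counted as higher above percentile 95, and as lower below percentile 5, of 10000 random lists matched on mean expression. This gave 11 higher and 3 lower of 23 lists, or 10 higher and 7 lower with TMM or DESeq2 scaling. In the simulations 10% of lists with no difference fell outside the limits, but genes were drawn there independently of each other. Genes of a real list can shift together, so this 10% is not an error rate for these calls. With 1 library on each side these are descriptions of the libraries and have no replicate check. NF-kB feedback genes lost their place with the read-based transcript table (percentile 8.0), and nuclear long noncoding genes lost theirs under several settings, such as a mean TPM of 5 or more (percentile 25.4).

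**Figure D4:**
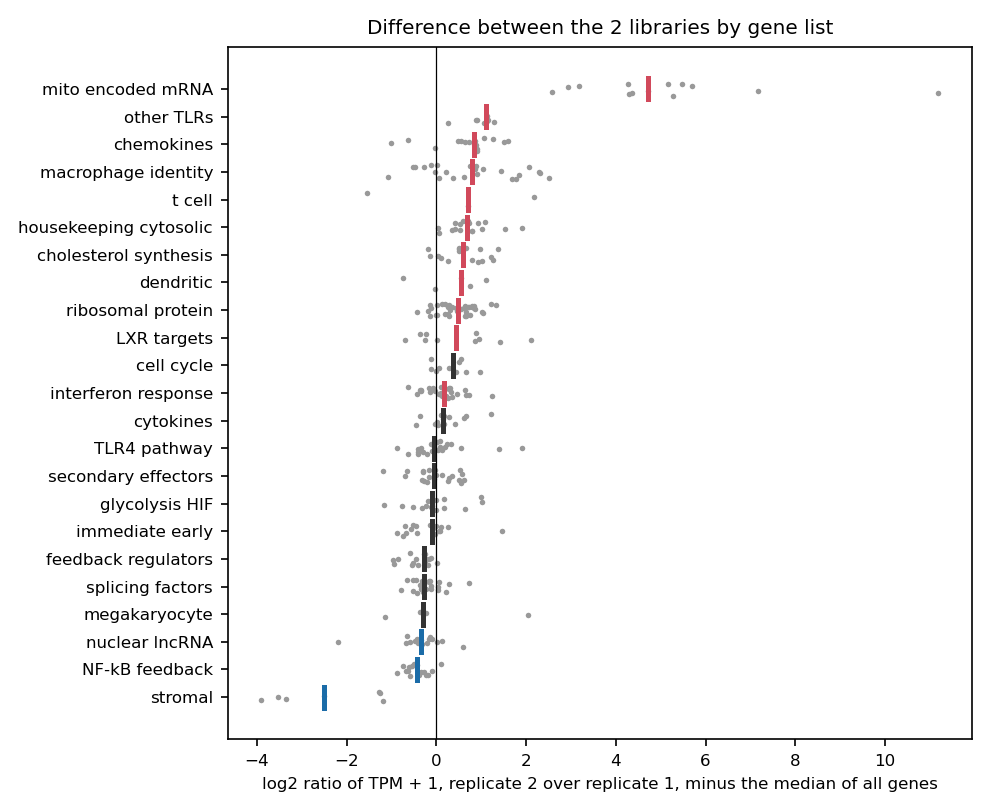
Log2 ratio of TPM + 1, replicate 2 over replicate 1, minus the median of all genes, for list members at a mean TPM of 1 or more. Points are genes and bars are list medians, red above percentile 95 and blue below percentile 5 of expression-matched random lists, dark in between. Mitochondrially encoded mRNA lies at 4.71 and the stromal list at -2.51, while interferon response and dendritic cell genes (0.16 and 0.55) turn negative without a filter on low values, at percentiles 99.8 and 35.9.

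Transcripts annotated as retaining an intron made up a large part of many genes' RNA. Over 3788 protein-coding genes at 5 TPM or more in both libraries, their median share of a gene's TPM was 39.3% in replicate 1 and 33.0% in replicate 2 (36.1 ± 4.42%). The share was lower in replicate 2 for 2738 genes and higher for 1013. Over 57 protein-coding toll-like receptor response genes the medians were 39.0% and 32.3%. Tnip3 (89.5% and 86.4%), Cd83 (83.0% and 82.2%), a dendritic cell maturation marker, and the interferon regulator Irf7 (79.5% and 80.0%) had the highest shares among these genes. Pde4b (0% in both), the interleukin 1 receptor antagonist gene Il1rn (4.74% and 2.05%) and Nfkb2 (5.99% and 3.85%) had the lowest. Mx2 (5.44% and 4.37%), which is not annotated as protein-coding, lay just below Nfkb2 on average. In splicing factor genes the median was 47.9% and 48.9%, with 11 of 24 lower in replicate 2, or 13 in the read-based table and 15 in estimated counts. In cytosolic housekeeping genes it was 24.8% and 13.7%, lower in 15 of 15, and Actb went from 33.2% to 13.7%. In nuclear RNA, reads of unspliced precursor that fall in such an intron are also assigned to these transcripts, and Irf7 and Nfkb2 overlap genes on the other strand (Phrf1 and Psd). Measured in estimated counts rather than TPM, the overall medians were 24.6% and 19.6%.

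The transcript tables of each library, 1 from a transcriptome alignment and 1 from the read files, ranked protein-coding genes more alike than all genes, and gave microRNA genes and processed pseudogenes different shares. Over genes at 1 TPM or more in either table, the Spearman correlation across genes was 0.554 in replicate 1 and 0.565 in replicate 2. Over protein-coding genes alone it was 0.848 and 0.865. MicroRNA genes held 0.0298% and 0.00934% of TPM in the alignment-based table but 26.6% and 28.7% in the read-based table. Processed pseudogenes held 0.752% and 0.346% against 10.7% and 15.9%. Malat1 had a mean of 20727 TPM, Tnf 209.3 TPM and Cd40 607 TPM in the read-based table, so single-gene TPM depends on the table used. In 8 of the 20 lists other than marker lists another gene led in the read-based table, among them Mx1 for interferon response, Ccl5 for chemokines and Gadd45b for feedback regulators.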

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

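Of the tests in this part, those on nuclear copies of mitochondrial DNA, on housekeeping genes and on all fibroblast matrix genes without a filter were chosen only after the result was seen; the other tests were set down before their values were looked at, on patterns found in these data.

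Entries kept apart from the annotated genes held some signal, while the 96 ERCC spike-ins among them had 0 counts. The phiX174 genome, a sequencing control, took 1.41% of all counts in replicate 1 and 0.245% in replicate 2. Entries with a number as identifier had 17 counts in replicate 1 and 11 in replicate 2 over all 26248 of them together, above the 3 counts that 0 allows for their sum, and no source used here says what they are.

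Mitochondrially encoded and macrophage identity RNA was higher in replicate 2, at relative log2 ratios of 4.71 and 0.80. Transcript length and GC content were removed only in other genes. There, mRNAs of secreted and membrane proteins exceeded those of soluble intracellular proteins by 0.86 (95% bootstrap interval 0.53 to 1.22) after removal. That argues against length or GC content as the whole cause of this difference, and does not cover the mitochondrial and macrophage identity genes. Their lists stayed above percentile 95 with matching on expression, length and GC content, a setting chosen after seeing the data. Reads shared with nuclear copies of mitochondrial DNA are argued against for the mitochondrial genes, since genes and copies together still differed by a log2 of 4.56. Cytoplasmic RNA carried into the fraction of replicate 2 may account for part of the higher RNA there. The unadjusted difference between secreted or membrane and soluble intracellular genes was 0.84 (0.56 to 1.19, 40 genes each, none in the fixed lists). A two-sided permutation of genes gave p = 1e-05, the smallest 100000 permutations can give. Whether such carried RNA was RNA at the endoplasmic reticulum or cytoplasmic RNA of every kind cannot be told apart. Cytosolic housekeeping (0.69, 18 of 18) and ribosomal protein genes (0.47) were higher too. The secreted and membrane group exceeded housekeeping genes by only 0.29 (0.02 to 0.66, permutation p = 0.135). These intervals and p-values measure spread among genes, with 1 library on each side, and not spread between cultures. Small RNAs lay outside these tests and were named after their values were seen. From replicate 1 to 2, Rn7sk, which restrains transcription elongation, went from 0.338% to 3.48% of counts. Rpph1, the RNase P RNA gene, went from 0.0617% to 0.861%. The 7SL RNA genes Rn7s1 and Rn7s2 went from 0.278% each to 0.483% and 0.530%. Whether carried RNA accounts for any of these was not tested. RNA input goes with the replicate, a difference between the cultures stays open, and no biological explanation was tested.

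Stromal marker RNA was present in replicate 1 and nearly gone in replicate 2, with 4808 and 30 counts over 11 genes. RNA of stromal cells in replicate 1 may be the source, as a separate list of 24 measured fibroblast matrix genes, none in the fixed lists, had 3413 and 176 counts, a log2 ratio of shares of -4.46 with 24 of 24 lower in replicate 2. Its median relative log2 ratio of -1.41 adds little, since all 12 members at a mean of 1 TPM lay below 1 TPM in replicate 2. Sparc had 415 and 2 counts, a gene chosen after its values were seen. Whether these reads came from cells in the culture or from another library was not tested, and no biological explanation was tested.

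MicroRNA genes held 26.6% and 28.7% of TPM in the read-based table. Very short effective lengths may inflate these values, since the same genes held at most 0.664% of its estimated counts. No biological explanation was tested.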

How the results depend on the processing

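The background of nuclear protein-coding genes, matching on length and GC content together with expression, the joint count with nuclear copies, agreement over nuclear protein-coding genes and the coefficient of variation with no TMM scaling were tests chosen after seeing the data. The limit of retained-intron shares to protein-coding genes was not in the rule fixed in advance. Shares over genes of any class followed that rule, but are counted with the added values below. Of the values under settings fixed in advance for results that answer a comparison, 422 counted as unchanged. Another 18 lost a place outside the limits, 28 gained one, 24 moved and 2 reversed. Of the added ones these numbers were 48, 1, 3, 0 and 0. Unchanged meant the same side of the limits for lists, and a change within a set tolerance for other results. For shares of counts the tolerance was the SD of the 2 libraries. Leaving out a library then counted as unchanged by construction, even for mitochondrially encoded genes at 0.424% and 8.70%. FPKM differs from TPM by 1 factor per library, so list levels and agreement could hardly change under it. Its unchanged values therefore say little. The cause was not tested unless stated. No paired analysis was possible because there is 1 group, and leaving out a library gives no value for agreement or for differences between replicates.

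With no filter on low values, interferon response (-0.12) and dendritic cell genes (-0.17) reversed. The median of all genes is then -0.31 instead of -0.58, a shift that alone turns the interferon sign, and interferon genes stayed at percentile 99.8. For dendritic cell genes that shift is too small, and low members also enter. There the T cell list stood at 0.26 inside the limits and cell cycle at 0.17 outside. The Spearman correlation of the replicates was 0.897 with no filter beyond a count above 0.

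As shares of TPM, means of the 2 libraries, nuclear protein-coding genes held 25.3%, ribosomal protein 0.287%, long noncoding 7.39%, small nuclear RNA 17.0%, small nucleolar RNA 6.94%, misc_RNA 20.2%, ribozymes 11.6%, TEC loci 1.06%, Malat1 3.19%, Rn7sk 12.8%, the top 10 genes 26.3% and the top 100 genes 50.4%, since division by length raises short RNA. One library decides several of these: replicates 1 and 2 held 2.87% and 22.7% for Rn7sk, 9.03% and 31.4% for misc_RNA, 11.6% and 2.26% for small nucleolar RNA, 11.0% and 3.82% for long noncoding, 1.54% and 0.585% for TEC loci, and 16% and 36.6% for the top 10. Among genes of effective length above 200, small nuclear RNA, small nucleolar RNA and ribozymes held 0% and misc_RNA 8.43e-05%, by construction. At 5 TPM, 6240 genes were detected.

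Against detected protein-coding genes, or detected genes of any class for nuclear long noncoding RNA, several lists no longer stood high. They lay at percentile 38.1 (immediate early), 86.8 (other toll-like receptors), 71.1 (nuclear long noncoding), 11.7 (cholesterol synthesis) and 87.5 (liver X receptor targets). Alternative activation, cell cycle and all 10 marker lists lay at 0, by construction where the median is below 1 TPM (10 of these 12). With members filtered likewise, immediate early lay at 61.3, other toll-like receptors at 93.7, cholesterol synthesis at 12.8 and cell cycle at 0.140. With the read-based table, cholesterol synthesis lay at 93.7, erythroid at 4.55 and mast cell at 2.77.

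For differences between replicates, TMM scaling put outside the limits immediate early (-0.23), feedback regulators (-0.29), splicing factors (-0.18) and megakaryocyte (-0.68), and DESeq2 scaling the same lists (-0.25, -0.30, -0.18 and -0.94), while the T cell list fell inside (0.43 and 0.48). With the read-based table, immediate early (-0.21) moved outside, and NF-kB feedback (-0.38), nuclear long noncoding (-0.21) and dendritic cell genes (0.29) inside. A pseudocount of 0.1 put cytokines (0.23) outside and nuclear long noncoding (-0.24) inside. Nuclear long noncoding also fell inside at a mean TPM of 5 or more (-0.14), with TPM rescaled to nuclear protein-coding genes (-0.24) and with matching on length and GC (-0.34), and the rescaling put cell cycle (0.39) outside. Feedback regulators moved outside with matching on length (-0.27) and in the nuclear protein-coding background (-0.34), as did splicing factors there (-0.35) and with matching on length and GC (-0.28).

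In estimated counts the retained-intron share, as the mean of the library medians, was 22.1% over all protein-coding genes and 29.6% over response genes. The median over genes of each gene's own difference, replicate 2 minus replicate 1, was -2.89 and -2.40 points instead of -4.78 and -4.03. This median of differences is not the difference between the library medians. Over genes of any class (3818 and 58) the share of TPM was 36.2% and 35.4%, with median differences of -4.72 and -3.98 points. The Spearman correlation between the transcript tables was 0.489 at 5 TPM or more and 0.856 over protein-coding genes. For named genes, 37 of the mean TPM values moved by more than 1 SD in the read-based table. Depth limits low genes: Csf3 rests on 2 and 3 counts.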

Other observations

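None of the groups in this part was planned; all were chosen after seeing the data.

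Lysosomal genes were higher in replicate 2 as a group. Over 18 genes, with none in the fixed lists, the median relative log2 ratio was 1.16 with 16 higher, and the counts were 63773 and 187745. Psap, which encodes the precursor of the saposins, stood at 1.80, the acid ceramidase gene Asah1 at 1.92, and the lysosomal lipase gene Lipa at 1.78. Ctsc (-0.06) and the proton pump subunit gene Atp6v1h (-0.23) were the members that did not follow. Soluble intracellular protein genes stood at 0.14 and genes of proteins made at the endoplasmic reticulum at 0.98, both above percentile 95 of matched lists.

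Nuclear RNA of X inactivation was abundant in both libraries, with Xist at 160879 and 99508 counts. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together had 20 counts in replicate 1 and 0 in replicate 2, which allows up to 3. Of 67 replication-dependent histone genes, 15 reached 1 TPM in both libraries, and the highest was Hist3h2a at 14.9 ± 0.262 TPM (SD, n = 2). The host gene of microRNA 155, Mir155hg, stood at 325 ± 1.68 TPM, with a relative log2 ratio of 0.59.

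Abundant small RNAs gave the following counts in replicates 1 and 2. Rn7sk had 48577 and 570499 counts, and the RNase P RNA gene Rpph1 had 8864 and 141024. The 7SL RNA genes Rn7s1 and Rn7s2, close copies whose reads cannot be divided with certainty, had 39926 and 79035 counts and 39926 and 86755 counts. The ribozyme annotation of Rmrp, the RNA of RNase MRP, had 101941 and 82786, and its overlapping lincRNA annotation 48649 and 6450 counts.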
